A study of Mus musculus with 53 samples.

How the data were processed

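The series measured messenger RNA in adult mouse hearts by RNA sequencing of a pair of fractions. Input was total cytoplasmic RNA. TRAP was RNA recovered by translating ribosome affinity purification, in which a tagged ribosomal protein, switched on by Cre recombinase, lets the ribosomes of chosen cells be pulled out together with the RNA bound to them. CAG mice carry the tag in all lineages, and Tie2 mice carry it in endothelial cells, as the labels of the first deposit describe these lines. Surgery either tied the ascending aorta against a needle (band), which overloads the left ventricle with pressure, or repeated the operation without the ligature (sham), in male mice per the labels' protocols. The sex of the mice without surgery was not given. Per the labels' protocols, pooled RNA went through poly(A) selection, random hexamer priming and a library preparation that does not mark strand, so reads of overlapping or antisense genes cannot be separated.

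The series lists 53 samples, 29 in a first deposit and 24 in a later one. The table analysed here holds 12 libraries and 0 columns of other samples. As a set its columns match the conditions and numbers of the later deposit, and the names CAG input, CAG TRAP and Tie2 input fit only that deposit, while the other names alone would also fit samples of the first deposit under the same condition. All were taken as libraries of the later deposit. Those titles end in l1 or l2 for each library, and what these endings mean and how they became a single column was not given in the sources used here. The comparisons within the first deposit, including those of cardiomyocyte TRAP RNA, were not analysed here. The 12 libraries were 2 each of CAG sham input, CAG sham TRAP, CAG band input and CAG band TRAP, and 1 each of CAG input, CAG TRAP, Tie2 input and Tie2 TRAP without surgery.

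RPKM values (reads per kilobase of transcript, scaled to the reads of the library) were deposited by the authors for 34306 genes, each with the identifier and length of 1 transcript. Reads were processed with CASAVA 1.8.2, TopHat 1.4 and HTSeq 0.5.3 and the genome build NCBIM37, per the submitters' processing notes, which give no order, annotation or settings. No genome of that build was used here, and genes carry the symbols and transcript identifiers of the table. In the table, 25 symbols had the form of a date. RPKM multiplied by length fell on whole multiples of the value of 1 read, within a tolerance of 0.02 reads, for 233410 of 233410 positive values, so the whole reads behind each value could be recovered. The recovered totals ran from 26568988 to 94878619 reads per library. A count of 0 in a library allows up to 3 reads by the 95% Poisson limit, and such floors cover counting error only.

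From the RPKM values, log2(RPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (moderated, with a trend of the variance over the mean level, two-sided) in 1 fit over the 12 libraries with a mean for each group. Genes at 1 RPKM or more in at least 2 libraries were kept, 11654 in all. Values of p were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. The fit had 4 residual degrees of freedom, to which limma's prior added 3.02. Its estimate of spread was shared by all groups. Comparisons with a group that varied more than the others may therefore have p-values that are too small. A fold change on the log2(RPKM + 1) scale understates the change of genes near or below 1 RPKM. Nothing in the labels says that the libraries of a group came from separate mice, and RNA was pooled, so p-values measure only the spread between these libraries, which may be technical. Replicate pairs differed by more than counting noise, and none was treated as a duplicate.

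The 5 tested comparisons were TRAP against input after sham surgery, TRAP against input after banding, band against sham in input RNA, band against sham in TRAP RNA, and the interaction, which is the change of the TRAP to input ratio with banding. The comparison of TRAP with input after banding was fixed only for the first deposit and was added here. Comparisons with 1 library on each side have no replicate check and no p-value. They were Tie2 TRAP against Tie2 input and CAG TRAP against CAG input without surgery, and, added after seeing the data, Tie2 TRAP against CAG TRAP.

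Apart from the added comparisons, the comparisons, the test by limma on log2(RPKM + 1), the rule for named genes in tested comparisons and 25 gene lists were fixed before the data were examined. The lists were cardiomyocyte, endothelial, fibroblast, macrophage and leukocyte, smooth muscle and pericyte, epicardial and mesothelial, adipocyte, erythroid, Schwann cell, atrial myocyte, genes reported higher and genes reported lower under pressure overload, extracellular matrix and fibrosis, fatty acid oxidation, nuclear encoded oxidative phosphorylation, mitochondrially encoded, long noncoding and nuclear RNA, glycolysis, cytosolic ribosomal protein, translation factors, endoplasmic reticulum stress and chaperones, immediate early, inflammatory cytokine and acute phase, ion channel and calcium handling, and cell cycle. Lists were tested with limma's camera at its preset correlation between genes, adjusted over the lists of a comparison, and again with an estimated correlation. In single-library comparisons the median of a list was placed among the medians of 10000 random lists of the same size matched on mean expression, as a description of those libraries.

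Named genes were the 10 with the largest and the 10 with the smallest log2 fold change among called genes whose groups did not overlap, that had a mean of at least 5 RPKM in the higher group and that had an ordinary symbol. Up to 4 members of a list with the smallest p, Rpl10a and a few fixed heart genes were added. In single-library comparisons, where the rule was set after seeing the data, they were the genes with the largest and smallest log2 difference at 5 RPKM or more. Genes that share sequence with pseudogenes or close paralogs, such as ribosomal protein genes, Gapdh, the ferritin genes and the haemoglobin genes, are uncertain, because the counting could have split or dropped their reads. Some genes that the naming rule or the lists picked, and a test of a further explanation for the ferritin values, are not reported here.

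The fit was tested on simulated data before use, with 11429 unchanged genes among the 11654. For band against sham in input it recovered 6 of 67 genes changed by 1.5-fold, 47 of 67 changed by 2-fold and 58 of 66 changed by 4-fold, and called 4 unchanged genes. For the interaction it recovered 0, 20 and 43 of them and called 2 unchanged genes. Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter or a filter of 5 RPKM, rescaling by the median log ratio, quantile normalization, leaving out the mitochondrially encoded, haemoglobin and 10 most abundant genes, fits on the compared groups alone, limma's arrayWeights, the replicate number as a block, and each library left out in turn. Added after seeing the data were limma's voom on the recovered reads, removal of each library's length trend, crossed pairing, a fit without the libraries from mice without surgery, and list tests without each library of the compared groups in turn, with the length trend removed or without the most abundant genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the figures.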

Results

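Messenger RNA was measured in 12 sequencing libraries of adult mouse hearts. Input libraries hold total cytoplasmic RNA, and TRAP libraries hold the RNA pulled down with tagged ribosomes. CAG hearts, tagged in all lineages, gave 2 libraries each of input and TRAP RNA after sham surgery and after aortic banding, and 1 of each without surgery. Tie2 hearts, tagged in endothelial cells, gave 1 input and 1 TRAP library without surgery. Values are RPKM as deposited by the authors, given as the mean ± SD of 2 libraries (n = 2) or as the value of a single library.

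The libraries of sham input held 48867104 and 33043255 reads, those of sham TRAP 35411590 and 41816186, those of band input 28621316 and 36151104, and those of band TRAP 37940589 and 47591033. The CAG libraries without surgery held 26568988 reads for input and 94878619 for TRAP, and the Tie2 libraries 50271246 and 38719997. Rpl10a, the ribosomal protein usually tagged in TRAP, was read at 7.58 and 8.10 RPKM in sham input and at 8.22 and 9.61 RPKM in sham TRAP, and at 10.4 RPKM in Tie2 input against 29.0 RPKM in Tie2 TRAP. Whether the table counted the tagged copy is not given in the sources used here. Tnnt2, a cardiomyocyte sarcomere gene, was read at 18165 RPKM in Tie2 input and 1367 RPKM in Tie2 TRAP, and Cav1, a gene of endothelial caveolae, at 23.0 and 453 RPKM. Across genes, the libraries of a group correlated at 0.997 for sham input, 0.996 for sham TRAP, 0.995 for band input and 0.982 for band TRAP, where genes are not independent replicates. The median absolute log2 difference between the libraries of a group was 0.08, 0.10, 0.11 and 0.20 in the same order, so the band TRAP libraries differed most. The first principal component, 53.1% of the variance, set Tie2 TRAP apart from the other libraries, and the next, 25.6%, parted TRAP from input.

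TRAP was compared with input RNA in CAG hearts, first after sham surgery, to ask which transcripts differed in level between them. How evenly the tag was carried and recovered across cell types was not measured here. Differences in ribosome binding and in the recovery of cell types therefore cannot be told apart in these ratios. Transcripts made inside mitochondria were nearly absent from TRAP RNA. The mitochondrial mt-Co2, a subunit of cytochrome oxidase, stood at 181 ± 51.4 RPKM in TRAP and 20008 ± 803 RPKM in input, and mt-Nd3, a subunit of complex I, at 29.4 ± 4.56 and 8741 ± 3493 RPKM, 278-fold lower. Haemoglobin and some nuclear noncoding transcripts were also far lower in TRAP, with Hbb-b1 at 62.4 against 801 RPKM and Malat1, a nuclear long noncoding RNA, at 16.0 against 256 RPKM. The largest rise among the named genes was that of Mrps34, of the mitochondrial ribosome, at 148 ± 1.05 against 55.2 ± 2.57 RPKM, which is 2.65-fold (limma, adjusted p = 0.00934). Its call was lost without sham input library 1 (limma, adjusted p = 0.0613) and without sham TRAP library 1 or 2 (0.0533 and 0.0511). Mrpl20, of the same particle, was 2.17-fold higher and Ndufc1, of complex I, 2.20-fold higher. Of 11654 genes, 1763 were called higher in TRAP and 2852 lower by limma, 43 and 345 of them by more than 1 on the log2 scale.

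Of the mitochondrially encoded list, 15 of 15 genes were called lower in TRAP, with 15 lower when adjusted over the list alone, a median log2 fold change of -6.44 and limma camera adjusted p = 1.43e-10 (adjusted p = 0.278 with an estimated correlation). These transcripts took 15.3 and 14.0% of the reads of the sham input libraries and 0.147 and 0.293% of those of sham TRAP. Erythroid genes followed, with 5 of 5 lower, 5 when adjusted over the list alone, a median of -3.58 and adjusted p = 4.25e-05 by camera (adjusted p = 0.225 with an estimated correlation). Haemoglobin took 0.181 and 0.176% of the reads in input and 0.0144 and 0.0146% in TRAP. Alas2, which starts haem synthesis in red cells, stood at 7.53 RPKM in input and 0.605 RPKM in TRAP. In the list of long noncoding and nuclear RNA, 1 gene was called higher and 4 lower, as when adjusted over the list alone, and the list as a whole did not pass (median -0.12, camera adjusted p = 0.287). Its called members Malat1, Neat1 and H19 had log2 fold changes of -3.92, -2.39 and -3.14 with standard errors of 0.25, 0.16 and 0.28.

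Fibroblast, matrix, macrophage, smooth muscle and epicardial lists were lower in TRAP. Among random lists matched on level, in the single CAG pair without surgery, their medians lay at percentiles of 0.01, 0.01, 0.48, 2.47 and 48.32. The fibroblast list had 0 genes higher and 16 of 17 lower, 16 when adjusted over the list alone, with a median log2 fold change of -0.80 and limma camera adjusted p = 8.77e-07 (adjusted p = 0.122 with an estimated correlation). Mmp2, a matrix-cutting protease, stood at 12.1 against 28.0 RPKM, and Islr at 3.74 against 8.29 RPKM. Of 28 genes of extracellular matrix and fibrosis, 0 were higher and 21 lower, the same counts as when adjusted over the list alone, with a median of -0.73 and adjusted p = 5.38e-07 by camera (adjusted p = 0.279 with an estimated correlation). Col1a1, a chain of type I collagen, had a log2 fold change of -1.62 and stood at 10.4 against 33.9 RPKM. Macrophage and leukocyte genes had 16 of 19 lower, 16 over the list alone, with a median of -0.72 and camera adjusted p = 1.4e-06 (adjusted p = 0.279 with an estimated correlation). Csf1r, the receptor that maintains macrophages, stood at 4.78 against 12.4 RPKM, and Lyz2 at 44.5 against 88.2 RPKM. Smooth muscle and pericyte genes had 8 of 12 lower (median -0.51, camera adjusted p = 0.0172) and epicardial and mesothelial genes 5 of 5 (median -0.56, camera adjusted p = 0.0102), both also 8 and 5 when adjusted over the list alone and both at adjusted p = 0.225 with an estimated correlation. Pdgfrb, a pericyte receptor, stood at 4.64 against 10.1 RPKM.

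The remaining cell type lists did not pass. Endothelial genes had 3 higher and 6 lower of 28 (median -0.13, camera adjusted p = 0.792), with Erg, an endothelial transcription factor, at 3.66 against 8.47 RPKM and Gpihbp1, a capillary lipase anchor, at 91.3 against 60.7 RPKM, both called. Cardiomyocyte genes had 7 higher and 9 lower of 26, 9 and 9 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.521). Its median (0.02) and mean (-0.07) differed in sign, and the median was -0.11 with quantile normalization and -0.32 without the most abundant genes. Among them Csrp3, a muscle LIM protein, stood at 3921 against 2418 RPKM and Tnnc1, cardiac troponin C, at 7089 against 4589 RPKM. Myoz2, a protein of the sarcomere's Z disc, stood at 579 against 1392 RPKM, with a log2 fold change of -1.26 (limma, adjusted p = 0.000741). Myh6 and Myh7, the myosin heavy chains of the adult and the fetal ventricle, stood at 1758 against 3525 RPKM and at 452 against 904 RPKM (adjusted p = 0.00218 and 0.00322 by limma). Adipocyte genes had 1 of 6 lower, Schwann cell genes 0 of 3 past the test, and atrial myocyte genes 2 of 7 lower, with camera adjusted p of 0.319, 0.792 and 0.792.

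Nuclear encoded oxidative phosphorylation and cytosolic ribosomal protein genes were higher in TRAP. Nuclear encoded oxidative phosphorylation had 18 of 28 genes higher and 0 lower, 20 higher when adjusted over the list alone, with a median log2 fold change of 0.52 and camera adjusted p = 3.45e-08 (adjusted p = 0.225 with an estimated correlation). Cox5b, a subunit of cytochrome oxidase made in the cytosol, stood at 7693 against 4206 RPKM and Ndufs3, of complex I, at 677 against 408 RPKM. Cytosolic ribosomal protein genes had 35 of 76 higher and 1 lower, 40 and 1 when adjusted over the list alone, with a median of 0.43 and camera adjusted p = 2.05e-11 (adjusted p = 0.225 with an estimated correlation). Their median length was 932.5 bases, and genes of 500 to 1000 bases had median log2 ratios of 0.44 and 0.37 in the sham pairs. The ribosomal list thus lay near other transcripts of like length. The list tests were not matched on length or level. Rpl41 stood at 1964 against 1089 RPKM and Rpl35 at 117 against 70.1 RPKM, values that reads shared with pseudogenes make uncertain. Translation factors did not move as a list (1 higher and 3 lower of 23, camera adjusted p = 0.519), but Pabpc1, the poly(A) binding protein, stood at 30.3 against 62.5 RPKM and Eef1a1, the elongation factor, at 185 against 268 RPKM. Fatty acid oxidation had 5 of 22 higher, 4 when adjusted over the list alone, and did not pass (camera adjusted p = 0.234).

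Of the lists of stress and growth genes, 3 were lower in TRAP than other genes by camera, which was not matched on level. In the single CAG pair without surgery they were set against random lists matched on level. Their medians lay at percentiles of 0.84 for immediate early, 10.25 for inflammatory and 17.38 for cell cycle genes. Immediate early genes, which respond to stimuli within minutes, had 12 of 15 lower, 13 when adjusted over the list alone, with a median log2 fold change of -0.47 and camera adjusted p = 0.000393 (adjusted p = 0.225 with an estimated correlation). Jun stood at 12.1 against 21.1 RPKM and Klf2 at 16.9 against 30.6 RPKM. Inflammatory cytokine and acute phase genes had 11 of 13 lower, 11 over the list alone, with a median of -0.60 and camera adjusted p = 0.0012 (adjusted p = 0.409 with an estimated correlation). Cell cycle genes had 5 of 11 lower, 5 over the list alone, with a median of -0.35 and camera adjusted p = 0.0219 (adjusted p = 0.225 with an estimated correlation). The lists of glycolysis (0 higher, 4 lower, 0 and 2 over the list alone), chaperones (2 and 5), ion channels and calcium handling (2 and 3, 2 and 2 over the list alone), genes reported higher (3 and 7) and genes reported lower (3 and 2) under pressure overload did not pass, with camera adjusted p of 0.174, 0.801, 0.389, 0.408 and 0.408. Nppb, brain natriuretic peptide, was among the genes higher in TRAP, at 1548 ± 50.3 against 868 RPKM.

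**Figure D1:**
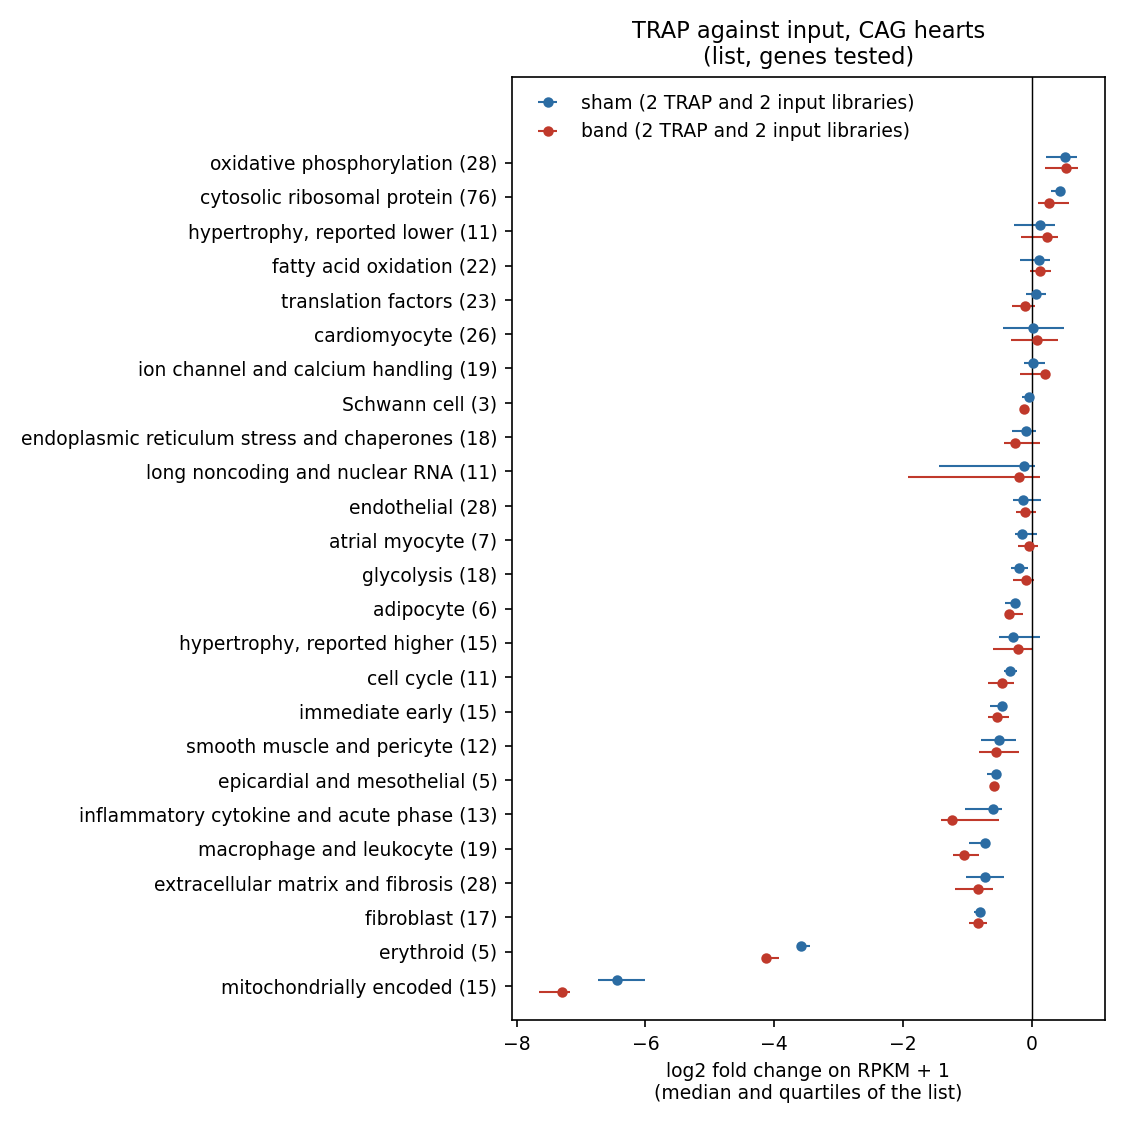
Median log2 fold change of TRAP against input RNA on RPKM + 1 (horizontal axis) for each gene list in CAG hearts after sham surgery (blue) and banding (red), with bars from the lower to the upper quartile over the list's tested genes, whose number is in parentheses. Mitochondrially encoded genes had medians of -6.44 and -7.29 and nuclear encoded oxidative phosphorylation genes of 0.52 in both.

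Transcript length moved with the TRAP to input ratio in CAG hearts. Over 5468 genes of 500 bases or longer and a mean of at least 5 RPKM, the slope of the log2 ratio per doubling of length was -0.22 and -0.18 in the sham pairs of same-numbered libraries, -0.18 and -0.17 in the band pairs and -0.26 without surgery, against -0.01 (SE 0.02) in Tie2 hearts. Between the libraries of 1 group and fraction it was between -0.01 and 0.04. With each library's length trend removed, 1567 genes were called higher and 1704 lower, and 2655 of these were also called without the removal. The count of calls also depended on single libraries, with 1917 and 2279 calls without sham input library 1 or 2 and 2240 and 2301 without sham TRAP library 1 or 2, where the lone library is taken to vary like the other groups. Leaving out the mitochondrial, haemoglobin and most abundant genes lowered the median of all genes by a shift of -0.17, and quantile normalization raised it by 0.14. Under the first 926 genes were higher and 4679 lower, and under the other 2053 and 1851, against 1763 and 2852 as tested. With a filter of 5 RPKM in at least 2 libraries, 1641 genes were higher and 1468 lower, so the balance depended on expression level too.

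**Figure D2:**
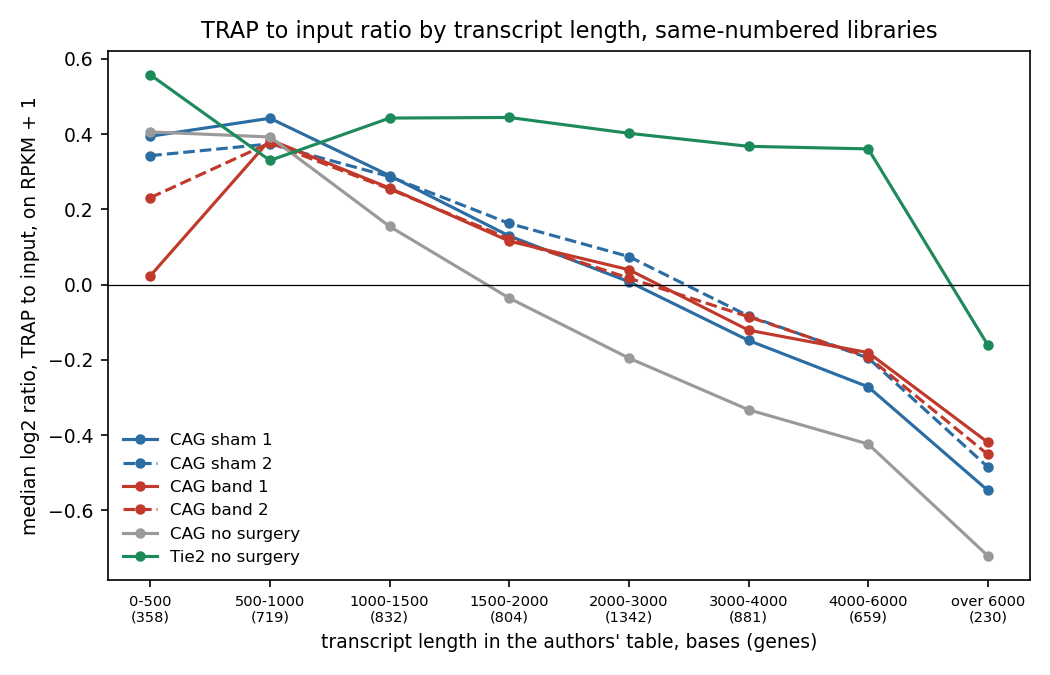
Median log2 ratio of TRAP to input on RPKM + 1 (vertical axis) over genes grouped by transcript length in bases (horizontal axis, number of genes in parentheses), 1 line for each pair of same-numbered libraries. In CAG hearts after sham surgery the first pair ran from 0.44 at 500 to 1000 bases to -0.55 above 6000 bases.

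After banding, mitochondrially encoded transcripts were again lowest in TRAP relative to input, with mt-Cytb, cytochrome b, at 95.3 ± 35.1 RPKM in TRAP and 19991 ± 1690 RPKM in input, and mt-Co2 at 102 ± 36.9 against 20336 ± 2160 RPKM. Highest in TRAP among the named genes was Gng5, a G protein subunit, at 3.98-fold. Rpl27, a ribosomal protein, stood at 165 ± 21 against 50.3 ± 3.06 RPKM. The complex I subunits Ndufb4, Ndufc1 and Ndufb2 were 2.95, 2.85 and 2.74-fold higher (limma, adjusted p = 0.000931, 0.000869 and 0.000756). Dnajc19, a mitochondrial import protein, was 2.87-fold higher and Hint3 2.87-fold higher. By limma 1938 genes were called higher and 3026 lower, 146 and 479 of them by more than 1 on the log2 scale. Of the called genes, 1410 were higher and 2335 lower after both operations, where independent lists would share 293 and 741.

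The mitochondrially encoded list was lower in 15 of 15 genes, 15 over the list alone (median log2 fold change -7.29, camera adjusted p = 1.57e-10, adjusted p = 0.224 with an estimated correlation). The erythroid list was lower in 5 of 5, 5 over the list alone (median -4.13, camera adjusted p = 4.14e-05, adjusted p = 0.224 with an estimated correlation). Mitochondrial reads made up 13.7 and 15.9% of band input and 0.138 and 0.0587% of band TRAP, and haemoglobin reads 0.108 and 0.136% against 0.00440 and 0.00763%. Extracellular matrix and fibrosis genes had 1 higher and 25 lower of 28, 1 and 25 over the list alone (median -0.83, camera adjusted p = 1.87e-08, adjusted p = 0.224 with an estimated correlation). Spp1, osteopontin, stood at 2.17 RPKM in TRAP against 13.1 RPKM in input, and Col1a1 at 12.3 against 46.6 RPKM. Fibroblast genes had 15 of 17 lower, 17 over the list alone (median -0.83, camera adjusted p = 1.88e-06, adjusted p = 0.139 with an estimated correlation). Macrophage and leukocyte genes had 17 of 19 lower, 18 over the list alone (median -1.05, camera adjusted p = 1e-07, adjusted p = 0.224 with an estimated correlation). Cd68, a macrophage lysosome protein, stood at 8.69 against 22.2 RPKM. Inflammatory genes had 11 of 13 lower over all genes, and 1 higher and 11 lower over the list alone (median -1.23, camera adjusted p = 0.000141, adjusted p = 0.283 with an estimated correlation). Among them Lgals3, galectin 3, stood at 3.06 against 16.2 RPKM. Nuclear encoded oxidative phosphorylation had 18 of 28 higher, 18 over the list alone (median 0.52, camera adjusted p = 9.99e-09, adjusted p = 0.224 with an estimated correlation). Cox6c stood at 3987 against 1638 RPKM. Ribosomal protein genes had 34 higher and 4 lower of 76, 36 and 4 over the list alone (median 0.26, camera adjusted p = 8.79e-08, adjusted p = 0.224 with an estimated correlation). Genes of 500 to 1000 bases, where the median length of this list lies, had median log2 ratios of 0.39 and 0.38 in the band pairs. Epicardial, immediate early and cell cycle genes were lower in 5 of 5, 11 of 15 and 7 of 11, or 5, 13 and 10 over the list alone, with medians of -0.59, -0.54 and -0.46 and camera adjusted p of 0.0171, 0.000786 and 0.00161 (adjusted p = 0.224 for each with an estimated correlation). Fatty acid oxidation had 6 higher and 1 lower of 22, 6 and 0 over the list alone, and passed at a median of 0.12 (camera adjusted p = 0.0299, adjusted p = 0.443 with an estimated correlation). Cardiomyocyte genes had 8 higher and 8 lower of 26 and did not pass (camera adjusted p = 0.487), with a median of 0.08 and a mean of -0.10. Smooth muscle and pericyte genes, called lower after sham surgery, had 7 of 12 lower and did not pass here (median -0.56, camera adjusted p = 0.0531).

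The scaling of the libraries decided part of this comparison. Quantile normalization ended the call of the ribosomal list, with a median of 0.15 and adjusted p = 0.0784 by camera, and that of the fatty acid list, whose test then pointed down (adjusted p = 0.744). Without single libraries, fatty acid oxidation was no longer called without band input library 2 or band TRAP library 1 (camera adjusted p = 0.0985 for each), nor epicardial genes without band TRAP library 1 (camera adjusted p = 0.0737). As tested, 1938 genes were higher and 3026 lower. Quantile normalization gave 2544 and 1955, and leaving out the most abundant genes 1084 and 4889. Removing each library's length trend gave 2064 and 2039, and a filter of 5 RPKM 1724 and 1560.

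Aortic banding was then compared with sham surgery in input RNA, to ask how cytoplasmic RNA of these hearts responded to pressure overload. Atrial transcripts were low in these inputs, with Myl7 at 15.8 RPKM on average after sham surgery and 23.6 and 12.5 RPKM after banding. It stood at 2724 and 5867 RPKM in the inputs without surgery, so this comparison says little about atrial tissue. The largest rise under the naming rule was that of Ankrd2, a stretch-responsive muscle protein, from 0.758 ± 0.0598 to 20.2 ± 4.14 RPKM. This is 12-fold on the log2(RPKM + 1) scale (limma, adjusted p = 0.00188). Spp1, osteopontin, rose 7.11-fold from 0.974 ± 0.0141 to 13.1 ± 1.59 RPKM, Timp1, an inhibitor of matrix proteases, 6.56-fold from 17.6 ± 1.04 to 121 ± 7.06 RPKM, and Ccl2, a chemokine that draws monocytes, 5.31-fold from 1.95 ± 0.0982 to 14.7 ± 1.70 RPKM. The mechanosensor Fhl1 rose 4.73-fold to 196 ± 27.1 RPKM and Nppb, brain natriuretic peptide, from 868 to 3297 RPKM (log2 fold change 1.92, SE 0.10, limma adjusted p = 0.000576). The acute phase gene Saa3 rose 5.18-fold, Itgb1bp3, an enzyme of NAD synthesis, 4.81-fold, Aldh1a2, which makes retinoic acid, 4.49-fold and Lgals3 4.0-fold. Among the genes that fell were Inmt, a methyltransferase, 2.63-fold, Rtn4r, the Nogo receptor, 2.33-fold, Scn4b, a sodium channel subunit, from 9.22 ± 0.994 to 4.5 ± 0.148 RPKM, and the globin Hbb-b2, uncertain among near-identical globins, from 226 ± 4.22 to 121 ± 15.1 RPKM (limma, adjusted p = 0.00643, 0.0013, 0.00643 and 0.02 in this order). Rps2, the largest fall under the naming rule at 3.14-fold, has many pseudogenes and is uncertain.

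Genes reported higher under pressure overload rose as a group, with 11 of 15 higher and 0 lower, 13 and 1 when adjusted over the list alone. The median log2 fold change was 1.05, and the limma camera test gave adjusted p = 7.79e-14 and held with an estimated correlation (adjusted p = 0.0283). Besides Nppb and Fhl1, Uck2, a uridine kinase, rose from 14.5 to 44.6 RPKM and Tnfrsf12a, the receptor of the cytokine TWEAK, from 45.9 to 130 RPKM. Nppa, atrial natriuretic peptide, stood at 140 and 138 RPKM in the sham libraries and at 261 and 459 RPKM in the band libraries and did not pass (limma, adjusted p = 0.191). Myh7, the fetal myosin, stood at 914 and 894 RPKM against 837 and 776 RPKM. Genes reported lower had 0 higher and 1 of 11 lower, 7 lower over the list alone, with a median of -0.29 and camera adjusted p = 0.00103 (adjusted p = 0.111 with an estimated correlation). The called gene, Kcnip2, a subunit of the channel that carries the transient outward potassium current, fell from 67.4 to 41.0 RPKM.

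Inflammatory cytokine and acute phase genes rose in 10 of 13 members, 13 over the list alone, with a median log2 fold change of 1.06 and camera adjusted p = 2.29e-16 (adjusted p = 0.111 with an estimated correlation). Serpina3n rose from 37.7 to 80.9 RPKM and Socs3, an inhibitor of cytokine signals, from 2.92 to 9.17 RPKM. Extracellular matrix and fibrosis genes rose in 10 of 28, 15 over the list alone (median 0.40, camera adjusted p = 1.44e-09, adjusted p = 0.199 with an estimated correlation). Thbs1, thrombospondin, rose from 0.209 to 2.05 RPKM and Col8a1, a collagen chain, from 2.70 to 7.86 RPKM. Macrophage and leukocyte genes rose in 5 of 19, 8 over the list alone (median 0.42, camera adjusted p = 3.68e-08, adjusted p = 0.205 with an estimated correlation). Cd68 rose from 12.2 to 22.2 RPKM and Cd52 from 26.4 to 50.8 RPKM. Immediate early genes had 8 higher and 1 lower of 15, 9 and 1 over the list alone (median 0.51, camera adjusted p = 1.38e-07, adjusted p = 0.111 with an estimated correlation). Atf3 rose from 1.98 to 5.88 RPKM and Myc from 0.961 to 2.66 RPKM. Cell cycle genes had 2 of 11 higher, 3 over the list alone (median 0.19, camera adjusted p = 0.00103, adjusted p = 0.111 with an estimated correlation). The called genes were Mcm5 and Mcm3 of the DNA replication helicase.

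Several lists shifted down by small amounts. Ion channel and calcium handling genes fell in 2 of 19, 9 over the list alone (median -0.26, camera adjusted p = 5.59e-05, adjusted p = 0.111 with an estimated correlation). Kcnip2 was among the called genes. Fibroblast genes had 1 higher and 4 lower of 17, 1 and 5 over the list alone (median -0.10, camera adjusted p = 0.0263, adjusted p = 0.182 with an estimated correlation). Fbln1 fell from 25.2 to 13.7 RPKM and Mfap5 rose from 7.18 to 13.6 RPKM. Endothelial genes had 0 of 28 called in either direction, with a median of -0.14 and camera adjusted p = 0.00399 (adjusted p = 0.185 with an estimated correlation). Erythroid genes had 1 of 5 lower, 3 over the list alone (median -0.54, camera adjusted p = 0.00399, adjusted p = 0.280 with an estimated correlation). Cardiomyocyte genes had 4 of 26 higher and 0 lower, 4 and 2 over the list alone, and did not pass as a list (camera adjusted p = 0.372). Csrp3 rose from 2418 to 4111 RPKM and Actc1, cardiac actin, from 4290 to 6129 RPKM. Epicardial genes had 1 of 5 lower, 2 over the list alone (median -0.31, camera adjusted p = 0.0152, adjusted p = 0.182 with an estimated correlation), and fatty acid oxidation 0 of 22 (median -0.10, camera adjusted p = 0.0257, adjusted p = 0.435 with an estimated correlation). Ribosomal protein genes had 1 higher and 1 lower of 76 (median 0.11, camera adjusted p = 0.000382, adjusted p = 0.280 with an estimated correlation). Nuclear encoded oxidative phosphorylation and mitochondrially encoded genes had 0 called genes (camera adjusted p = 0.317 and 0.949). Signs differed for 4 lists that did not pass. Smooth muscle and pericyte genes had a median of -0.05 and a mean of 0.13, Schwann cell genes a median above 0 and a mean of -0.02, and mitochondrially encoded and long noncoding genes a median and mean above 0 where camera pointed down.

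By limma 284 genes rose and 192 fell in input RNA, 62 and 11 of them by more than 1 on the log2 scale. The count was 42 and 26 without sham input library 1 or 2 and 67 and 47 without band input library 1 or 2, and it was 1491 when the input groups were fitted alone. Of 33 genes given as called, Gm10263 included, some lost their call when 1 library was left out. The calls of Hbb-b2, Kcnip2, Cd68, Cd52, Myc, Mcm5, Mcm3, Fbln1, Mfap5, Csrp3 and Actc1 were lost in each of the 4 fits. Those of Inmt, Scn4b, Thbs1, Col8a1 and Atf3 were lost in some, and the other genes kept theirs in each. The calls of the fibroblast and epicardial lists were lost without band input library 1 (camera adjusted p = 0.0520 and 0.0578), and that of fatty acid oxidation without sham input library 1 or band input library 2 (0.0554 and 0.136).

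**Figure D3:**
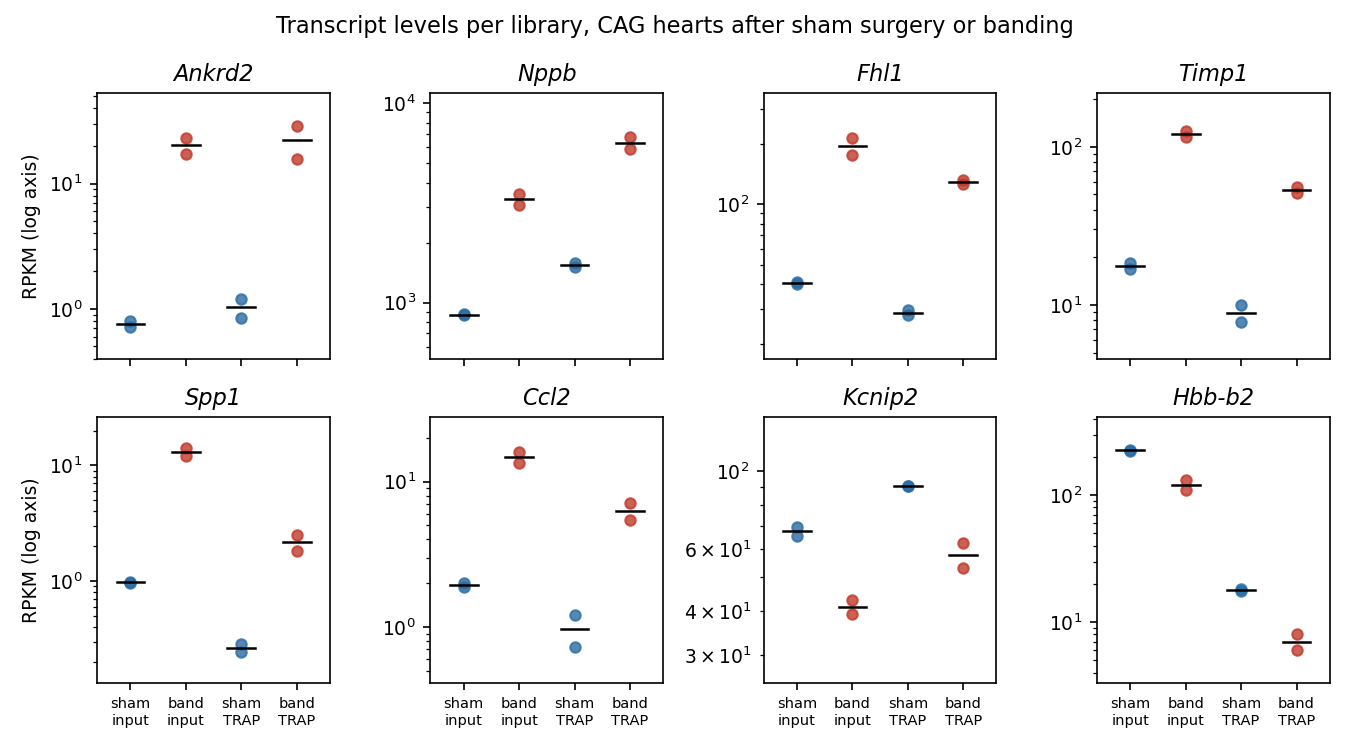
RPKM on a log axis (vertical) of 8 genes in the sham (blue) and band (red) libraries of input and TRAP RNA, with a point for each library and a line at the mean of 2. Ankrd2 stood at 0.758 RPKM in sham input and 20.2 RPKM in band input on average, and Hbb-b2 at 226 and 121 RPKM.

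The same comparison in TRAP RNA asked how RNA on ribosomes responded to banding. Ankrd2 again rose most under the naming rule, from 1.03 ± 0.254 to 22.4 ± 9.42 RPKM, 11.1-fold (limma, adjusted p = 0.00212). Timp1 rose 5.49-fold to 53.3 ± 3.53 RPKM, Itgb1bp3 5.45-fold, Saa3 4.44-fold, Fhl1 4.38-fold to 129 ± 3.27 RPKM, and Nppb 4.08-fold from 1548 ± 50.3 to 6330 ± 573 RPKM (limma, adjusted p = 0.000434 for Nppb). Uck2 rose 3.95-fold and Ccl2 3.72-fold. The largest fall under the naming rule was that of Snhg9, a noncoding RNA that hosts a small nucleolar RNA, from 19.2 ± 2.26 to 2.49 ± 0.0549 RPKM, 5.79-fold. Among the other falls were those of the globins Hba-a1, 3.15-fold, Hbb-b2, 2.37-fold, and Hbb-b1, 2.05-fold, whose reads near-identical copies could share, and that of Rtn4r, 3.10-fold. The myosin light chain Myl9 fell from 74.8 ± 2.77 to 38.6 ± 6.16 RPKM and Fabp5, a lipid carrier of endothelium and macrophages, from 15.7 ± 0.780 to 7.49 ± 1.65 RPKM (limma, adjusted p = 0.0101 and 0.0123). Gapdh rose 4.64-fold, but its band libraries spread widely (108 ± 61.8 RPKM) and its many pseudogenes make it uncertain.

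Genes reported higher under pressure overload rose in 10 of 15, 12 higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 0.93 and limma camera adjusted p = 3.41e-13, which held with an estimated correlation (adjusted p = 0.0297). Tnfrsf12a rose from 73.6 to 193 RPKM. Nppa stood at 182 and 167 RPKM after sham surgery and 194 and 571 RPKM after banding (limma, adjusted p = 0.338). Inflammatory genes rose in 8 of 13, 9 over the list alone (median 0.76, camera adjusted p = 2.86e-10, adjusted p = 0.196 with an estimated correlation). Serpina3n rose from 22.0 to 56.7 RPKM and Socs3 from 1.59 to 6.56 RPKM. Immediate early genes rose in 7 of 15, 9 higher and 1 lower over the list alone (median 0.50, camera adjusted p = 9.84e-08, adjusted p = 0.196 with an estimated correlation). Atf3 rose from 1.65 to 5.48 RPKM. Matrix genes rose in 6 of 28, 9 over the list alone (median 0.25, camera adjusted p = 2.65e-06, adjusted p = 0.326 with an estimated correlation). Spp1 rose from 0.265 to 2.17 RPKM. Macrophage and leukocyte genes rose in 2 of 19, 4 over the list alone (median 0.17, camera adjusted p = 0.00584, adjusted p = 0.503 with an estimated correlation).

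Erythroid genes fell in 3 of 5, 4 over the list alone (median -1.04, camera adjusted p = 7.71e-05, adjusted p = 0.207 with an estimated correlation). Haemoglobin took 0.0144 and 0.0146% of the reads of sham TRAP and 0.00440 and 0.00763% of those of band TRAP. Mitochondrially encoded genes had 0 of 15 called over all genes and 6 lower over the list alone (median -0.82, camera adjusted p = 0.000663, adjusted p = 0.503 with an estimated correlation). Mitochondrial reads were at 0.147 and 0.293% in sham TRAP and 0.138 and 0.0587% in band TRAP. Fibroblast genes fell in 3 of 17, 4 over the list alone (median -0.14, camera adjusted p = 0.0107, adjusted p = 0.196 with an estimated correlation). Clec3b fell from 74.3 to 42.6 RPKM. Ion channel and calcium handling genes had 1 higher and 2 lower of 19, 1 and 3 over the list alone (median -0.15, camera adjusted p = 0.0104, adjusted p = 0.196 with an estimated correlation). Kcnip2 fell from 90.9 to 57.7 RPKM and Hcn2, a pacemaker channel, from 10.3 to 5.11 RPKM. Endothelial genes had 0 called over all genes and 2 lower over the list alone (median -0.18, camera adjusted p = 0.00194, adjusted p = 0.196 with an estimated correlation). Genes reported lower under pressure overload had 1 of 11 lower, 2 over the list alone (median -0.30, camera adjusted p = 0.0111, adjusted p = 0.196 with an estimated correlation), and epicardial genes 1 of 5, 3 over the list alone (median -0.36, camera adjusted p = 0.0383, adjusted p = 0.207 with an estimated correlation). Glycolysis genes had 2 of 18 higher, 4 over the list alone, and the list did not pass (camera adjusted p = 0.292), its median (-0.03) and mean (0.18) differing in sign. Pfkp, the platelet form of phosphofructokinase, rose from 6.52 to 14.8 RPKM. Csrp3 and Actc1 of the cardiomyocyte list rose from 3921 to 6638 RPKM and from 3835 to 6281 RPKM, while the list did not pass (camera adjusted p = 0.186).

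By limma 257 genes rose and 182 fell in TRAP RNA, 61 and 29 of them by more than 1 on the log2 scale. These calls rest on a spread shared by all groups, so their adjusted p-values may be too small. The median absolute log2 difference between libraries was 0.20 in band TRAP, against 0.08 to 0.11 in the other groups. The count was 13 when the TRAP groups were fitted alone, 37 and 33 without sham TRAP library 1 or 2, and 1661 and 1967 without band TRAP library 1 or 2. The balance turned without band TRAP library 1, with 573 genes higher and 1088 lower, and without band TRAP library 2 it was 1085 and 882. Of 28 genes given as called, Gm10263 included, none changed sign in the fits without a library. The calls of Hba-a1, Hbb-b2, Hbb-b1, Myl9, Fabp5, Gapdh, Spp1, Clec3b, Kcnip2, Hcn2, Pfkp, Csrp3 and Actc1 were lost in some of these fits. The other genes kept theirs in each. Without band TRAP library 1 the calls of the fibroblast (camera adjusted p = 0.0724), macrophage (0.111), ion channel (0.111) and epicardial (0.182) lists were lost, and without sham TRAP library 2 those of the mitochondrially encoded (0.0968) and epicardial (0.0570) lists, the latter also without band TRAP library 2 (0.102).

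Whether banding changed the TRAP to input ratio itself was tested as an interaction. By limma 0 genes passed, with 557 at an unadjusted p under 0.05, a smallest adjusted p of 0.151 and 0 calls by limma's voom on the recovered reads. The smallest p belonged to Snhg9, Gm5566, Rpl21-ps11, Rps27a-ps2 and Mir5133, with log2 differences of -1.84, -1.12, -1.70, -0.98 and 2.24, none past the threshold. Spp1, whose input level rose 7.11-fold, had a difference of -1.51 (SE 0.19, limma adjusted p = 0.151), and Lgals3 one of -1.04 (SE 0.17, limma adjusted p = 0.302). Spp1 lay below 1 RPKM in sham TRAP. Adding 1 RPKM there shrinks its TRAP rise more than its input rise, so its difference is overstated on this scale. The responses of input and TRAP RNA to banding overlapped, with 161 genes higher and 93 lower in both, where independent lists would share 6.26 and 3.0, and 0 called in opposite directions. Of the genes called higher in input, 96.8% had a positive log2 fold change in TRAP, and of those called lower 97.4% a negative one. Across all 11654 genes the responses correlated at 0.598, and across the 476 called in input at 0.909, where genes are not independent replicates. By limma camera 7 of the 25 lists had a lower TRAP to input ratio after banding at the preset correlation, led by the mitochondrially encoded list (median -0.98, adjusted p = 0.000313), and 0 passed with an estimated correlation (adjusted p from 0.414 to 0.802). Mitochondrial reads took 0.147 and 0.293% of sham TRAP libraries 1 and 2 and 0.138 and 0.0587% of band TRAP libraries 1 and 2. The libraries numbered 1 were thus nearly alike. Whether so small a residue reflects ribosome binding or RNA carried over in the pulldown was not tested. The median and mean differed in sign for cardiomyocyte, Schwann cell, atrial and immediate early genes, none of which passed. The interaction gave 197 calls without band TRAP library 1 and 78 without band TRAP library 2. Of the 7 list calls, 4 were lost without band TRAP library 2, where the mitochondrially encoded list had a camera adjusted p of 0.0607.

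**Figure D4:**
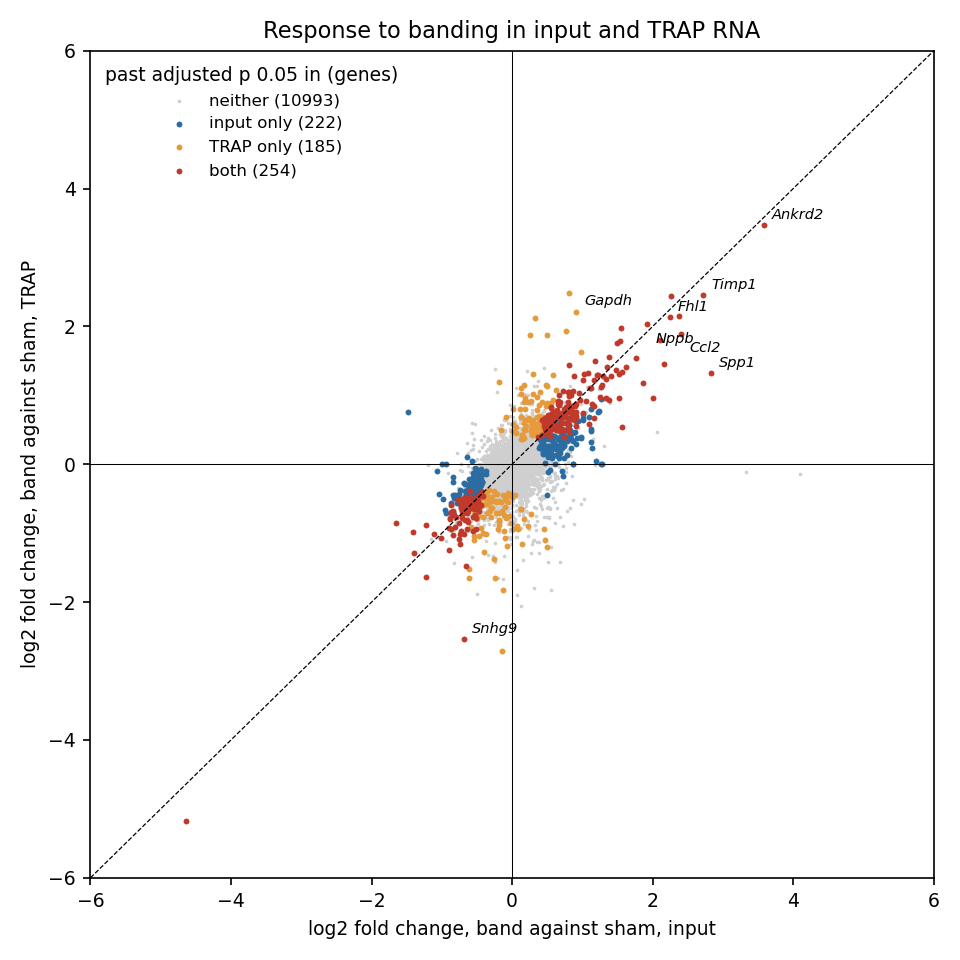
Log2 fold change of band against sham on RPKM + 1 in input RNA (horizontal axis) and in TRAP RNA (vertical axis), 1 point for each of 11654 genes, coloured by whether the gene passed an adjusted p of 0.05 in input (blue, 222), in TRAP (orange, 185), in both (red, 254) or in neither (grey, 10993). The dashed line marks equal responses, and Ankrd2 lies at 3.58 and 3.47.

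In Tie2 hearts without surgery, 1 TRAP library was compared with 1 input library, to ask which RNA the tagged endothelial ribosomes carry. Endothelial transcripts were far higher in TRAP. S1pr1, the endothelial receptor of sphingosine 1-phosphate, stood at 202 against 8.17 RPKM, 22.1-fold higher, Cav1, of the caveolae of capillaries, at 453 against 23.0 RPKM, Ly6c1, an endothelial surface protein, at 2421 against 129 RPKM, and Timp4, a protease inhibitor, at 545 against 19.7 RPKM, 26.4-fold higher. Cardiomyocyte transcripts were far lower, with Myl2, the ventricular myosin light chain, at 618 against 28102 RPKM, 45.4-fold lower, Tnnc1 at 249 against 9481 RPKM and Myl3 at 247 against 7867 RPKM. These differences have no replicate check.

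All 28 endothelial genes were higher in Tie2 TRAP than in Tie2 input, with a median of 9.68-fold on RPKM + 1, at the percentile of 100 among random lists. Macrophage and leukocyte genes, of blood cells that arise from Tie2-expressing ancestors, were higher in 19 of 19, with a median of 6.18-fold and the same percentile of 100. All 26 cardiomyocyte genes were lower, with a median of 13.5-fold and a percentile of 0, and stood at a median of 7.38% of their input level. Fatty acid oxidation genes were lower in 21 of 22 (median 5.83-fold) and nuclear encoded oxidative phosphorylation genes in 28 of 28 (median 6.34-fold), both at a percentile of 0. Mitochondrially encoded genes were lower in 15 of 15, 18.7-fold at the median and at 5.32% of input, and mitochondrial reads took 3.17% of Tie2 input and 0.183% of Tie2 TRAP. Ribosomal protein genes were higher in 73 of 76, with a median of 2.96-fold and a percentile of 100. Fibroblast genes were higher in 17 of 17 with a median of 1.75-fold, at a percentile of 79.9, and matrix genes in 27 of 28 at a percentile of 82.0. The median log2 difference of all genes was 0.48, and rescaling by the median log ratio shifted it by -0.38, leaving the endothelial median at 2.79 and the cardiomyocyte median at -4.24. The fibroblast and matrix medians, 0.81 and 0.68, were then 0.34 and 0.32, and they were 0.39 and 0.30 with quantile normalization and 0.35 and 0.23 with the length trend removed.

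**Figure D5:**
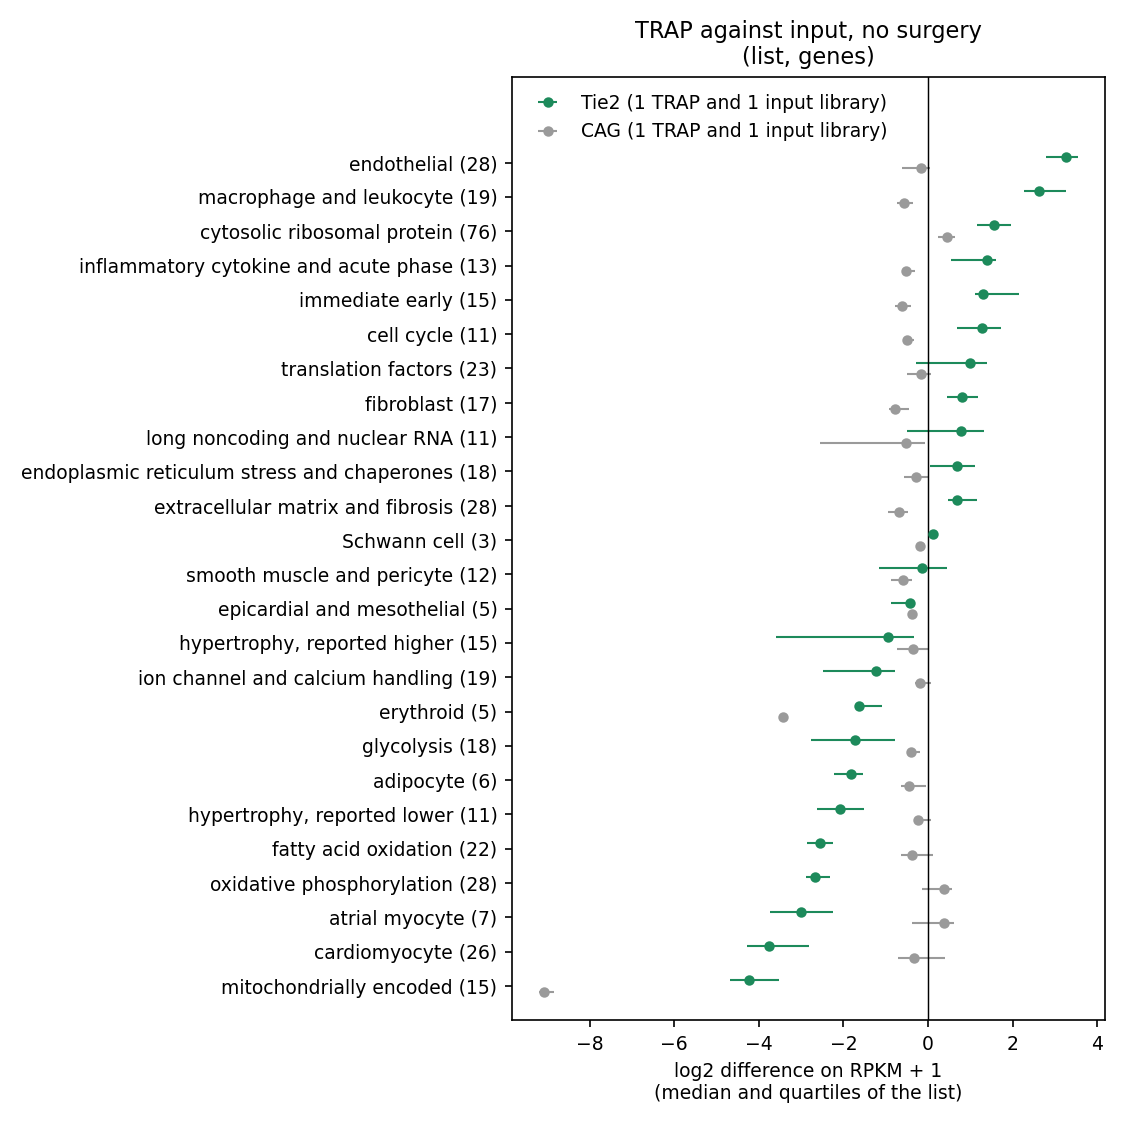
Median log2 difference of TRAP minus input on RPKM + 1 (horizontal axis) for each gene list in hearts without surgery, for the Tie2 pair (green) and the CAG pair (grey) of single libraries, with bars from the lower to the upper quartile over the list's genes, whose number is in parentheses. The endothelial list lay at 3.28 in Tie2 and -0.17 in CAG hearts.

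In CAG hearts without surgery, also with 1 library on each side, mitochondrially encoded genes were 538-fold lower in TRAP at the median, with 15 of 15 lower, and took 14.3% of the reads in input and 0.0259% in TRAP. Erythroid genes were 10.7-fold lower in TRAP at the median, 5 of 5 lower, with 0.101% of reads in input and 0.00804% in TRAP. Both lists lay at a percentile of 0 among random lists. Fibroblast genes were lower in 16 of 17 (median log2 difference -0.77), matrix genes in 26 of 28 (-0.68) and macrophage and leukocyte genes in 18 of 19 (-0.57). Ribosomal protein genes were higher in 68 of 76 (0.46, percentile 95.7), and nuclear encoded oxidative phosphorylation genes in 17 of 28, with a median of 0.38 that lay at a percentile of 24.8 among random lists. Fatty acid oxidation genes were lower in 15 of 22 (-0.38, percentile 0) and cardiomyocyte genes in 15 of 26 (-0.32, percentile 0.02). Mrps34 stood at 122 against 36.1 RPKM and Snhg9 at 68.2 against 9.46 RPKM, the latter 6.62-fold higher in TRAP.

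The size of several of these medians depended on the scaling of the CAG pair. Quantile normalization shifted the median of all genes by 0.32 and gave fibroblast, matrix and macrophage genes medians of -0.50, -0.40 and -0.29 and oxidative phosphorylation genes 0.18, and a pseudocount of 5 RPKM gave the former 3 lists -0.42, -0.37 and -0.35. With the length trend removed, a shift of 0.28, fibroblast genes stood at -0.49, matrix genes at -0.19 with 20 of 28 lower, fatty acid oxidation genes at -0.13 and cardiomyocyte genes at -0.06. Rescaling by the median log ratio, a shift of 0.20, gave medians of -0.35 for macrophage, 0.74 for ribosomal protein, 0.66 for oxidative phosphorylation, -0.09 for fatty acid oxidation and -0.04 for cardiomyocyte genes, of which 13 were higher and 13 lower. Without the most abundant genes, a shift of -0.15, ribosomal protein genes stood at 0.28, oxidative phosphorylation genes at 0.20, and fatty acid oxidation and cardiomyocyte genes at -0.56 and -0.60.

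Between the TRAP libraries without surgery, endothelial genes were higher in Tie2 than in CAG in 28 of 28, with a median of 14.4-fold, and macrophage and leukocyte genes in 19 of 19, with 11.6-fold. Cardiomyocyte genes were lower in 25 of 26, with a median of 9.36-fold. The median log2 difference of all genes was 0.85. Rescaling by the median log ratio shifted that median by -0.63 and moved the endothelial, macrophage and cardiomyocyte medians from 3.85, 3.54 and -3.23 to 3.02, 2.77 and -4.01. Removing the length trend gave 3.04, 2.90 and -3.92, and quantile normalization gave 3.40, 2.89 and -3.73. Aqp1, a water channel of capillaries, stood at 1408 against 45.3 RPKM and Fcer1g, an immune receptor chain, at 331 against 9.19 RPKM. Igf2, a growth factor, stood at 293 against 6.74 RPKM, 38.0-fold higher. Myl2 stood at 618 against 32371 RPKM and Nppb at 36.0 against 1880 RPKM, 52.3 and 50.8-fold lower.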

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

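The list tests without 1 library in turn, without the most abundant genes and with the length trend removed were chosen only after the results were seen. The change of the TRAP to input ratio with banding was tested for the 25 gene lists, and 7 differed between sham and band hearts by limma's camera test at its preset correlation. All 7 had lower ratios after banding, 0 passed with an estimated correlation, and 0 genes passed by limma when adjusted over all genes tested, with 557 at an unadjusted p under 0.05 and 0 by voom. Mitochondrially encoded genes had a median log2 difference of -0.98 over 15 genes (camera adjusted p = 0.000313, adjusted p = 0.802 with an estimated correlation). Their few reads in TRAP may be RNA carried over in the pulldown, which was not tested. For macrophage and leukocyte genes the median log2 difference was -0.23 over 19 genes (camera adjusted p = 0.000602, adjusted p = 0.802 with an estimated correlation). Inflammatory cytokine and acute phase genes stood at -0.30 over 13 genes, 2 of them past the test when adjusted over the list alone (camera adjusted p = 0.00174, adjusted p = 0.802 with an estimated correlation). Extracellular matrix and fibrosis genes stood at -0.13 over 28 genes, 1 of them past the test when adjusted over the list alone (camera adjusted p = 0.00522, adjusted p = 0.802 with an estimated correlation). Cell cycle genes stood at -0.22 over 11 genes (camera adjusted p = 0.00522, adjusted p = 0.414 with an estimated correlation), translation factors at -0.18 over 23 genes (0.0102 and 0.414) and erythroid genes at -0.49 over 5 genes (0.0377 and 0.802).

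Without single libraries 6 of the 7 lists lost their call at least once. Without band TRAP library 2, the calls of the macrophage (camera adjusted p = 0.135), matrix (0.343), mitochondrially encoded (0.0607) and inflammatory (0.0930) lists were lost. Without band TRAP library 1, the erythroid (camera adjusted p = 0.576) and cell cycle (0.304) lists no longer passed. The erythroid list was also lost without sham input library 1, sham TRAP library 1 or band input library 2 (camera adjusted p = 0.0614, 0.138 and 0.216), and the mitochondrially encoded list without sham TRAP library 2 (0.0868). Translation factors passed in each of the 8 fits. A pseudocount of 0.1 RPKM ended the calls of the matrix (camera adjusted p = 0.164), inflammatory (0.330) and cell cycle (0.142) lists. Quantile normalization, rescaling by the median log ratio and removal of the length trend each ended that of the erythroid list (0.0999, 0.0676 and 0.0534). The band TRAP libraries also differed in the Y-linked Eif2s3y, at 5.23 RPKM in library 1 and 0.499 RPKM in library 2, and Ddx3y, at 2.85 and 0.915 RPKM, and less in Kdm5d, at 0.530 and 0.399 RPKM. Uty stood at 0.354 and 0.0565 RPKM, and Xist, which female cells express, at 0.00309 and 0 RPKM, and the labels give male mice for surgery. The band input libraries 1 and 2 were closer to each other. They held Eif2s3y at 3.75 and 3.61, Ddx3y at 2.69 and 3.46, and Kdm5d at 0.485 and 0.410 RPKM.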

How the results depend on the processing

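The fits by voom, with the length trend removed, without the no-surgery libraries and with crossed pairing, and the list tests without the most abundant genes, with the length trend removed or without single libraries, were chosen only after the results were seen. Of 615 list results under other settings with all libraries, 591 stayed on their side of the threshold, 12 lost a call, 11 gained one and 1 reversed, which was fatty acid oxidation in TRAP against input after banding, whose camera direction turned with quantile normalization at a median of 0.00251 (adjusted p = 0.744). With an estimated correlation 70 of 125 list results were as before and 55 lost their call, and only genes reported higher under pressure overload held, in input and in TRAP RNA. A call lost this way need not mean correlated genes. In TRAP against input after sham surgery, the fibroblast list went from a camera adjusted p of 8.77e-07 to 0.122, although its estimated correlation was -0.0076. In every fit without a single library, 12 of 12 called lists passed in TRAP against input after sham surgery, 10 of 12 after banding, 11 of 14 in band against sham input, 7 of 12 in TRAP RNA and 1 of 7 for the interaction. Named genes gave 2070 results under other settings, of which 1901 were as before, 150 lost and 19 gained a call and 0 reversed.

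The count of genes differing between TRAP and input after sham surgery (4615) stayed within 1.5 times in every setting with all libraries, at 3109 to 6862, and was 1917 and 2279 without sham input library 1 or 2 and 2240 and 2301 without sham TRAP library 1 or 2. After banding (4964) it was 3284 with a filter of 5 RPKM, 2503 with the compared groups fitted alone and 3123 with arrayWeights, and from 2767 (without band input library 1) to 6260 (without band TRAP library 1). For band against sham in input (476) it was 1491 in the groups alone, 1599 with arrayWeights, 42 and 26 without sham input library 1 or 2, and 67 and 47 without band input library 1 or 2. In TRAP RNA (439) it was 207 without a filter, 13 in the groups alone, 142 with arrayWeights, 37 and 33 without sham TRAP library 1 or 2, and 1661 and 1967 without band TRAP library 1 or 2. The interaction (0 by limma, 557 at an unadjusted p under 0.05, 0 by voom) gave 2 calls with a pseudocount of 0.1 RPKM, Snhg9 and Mir5133, and 2 without a filter, Gm17253 and Hist1h3a, both below 1 RPKM in every library and all 4 named after their values were seen. It gave 197 and 78 without band TRAP library 1 or 2 and 0 without any other library. A group left with 1 library adds nothing to the shared estimate of spread, and the band TRAP libraries differed most. Calls gained without 1 of them are therefore no evidence of changes that this library hid. The cause of these shifts was not tested further.

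The endothelial median of Tie2 TRAP against input (3.28) was 3.41 and 3.0 with pseudocounts of 0.1 and 5 RPKM, 2.79 rescaled by the median log ratio, 3.14 with quantile normalization, 3.05 without the most abundant genes and 2.82 with the length trend removed, and the cardiomyocyte median (-3.76) was -4.24 rescaled and -4.15 with the length trend removed. The mitochondrial median of the CAG pair without surgery (-9.07) was -8.69 with a pseudocount of 5 RPKM, -8.80 rescaled and -8.70 with quantile normalization. The cause was not tested.

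Same-numbered libraries correlated in their deviations at -0.17, 0.030, -0.054 and -0.434, so the main fits did not use the numbers as pairs. With 2 libraries a group, these values cannot show whether same-numbered input and TRAP libraries came from the same hearts. With the replicate number as a block, 786 genes were called in band against sham input and 0 in TRAP RNA, where 867 had an unadjusted p under 0.05 by limma and voom without a block called 454, and in TRAP against input and the interaction the block moved no count by over 1.5 times. Crossed pairing called 3375 genes in TRAP against input after sham surgery and 47 in band against sham TRAP. Treating l1 and l2 as separate libraries and joining the first deposit to the later were not run, because the table holds a single column for each library of the later deposit. At these depths and with 2 libraries a group, simulated changes of the ratio were recovered for 0 of 67 genes at 1.5-fold and 20 of 67 at 2-fold. Changes of 2-fold or less were therefore not detectable for most genes. The simulation gave a gene the same spread in all libraries, while the real band TRAP libraries differed most, so comparisons with band TRAP may be recovered differently.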

Other observations

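Chosen only after the results were seen were the genes of this and the next paragraph, the fit with the length trend removed, the tests of length trends between libraries and of long RNA lost in the pulldown, and the atrial tests other than that of cardiomyocyte RNA. Some messenger RNAs lay far lower in TRAP than in input after sham surgery. Ybx1, which encodes an RNA-binding protein that packages messenger RNA, stood at 64.5 ± 5.04 against 518 ± 20.1 RPKM, 7.93-fold lower (limma, log2 fold change -2.99, SE 0.10, adjusted p = 1.85e-05). Its log2 fold change was -3.02 after banding, and the single pairs gave -2.95 in CAG and -1.93 in Tie2 hearts without surgery. Zc3h12a, a ribonuclease that cuts inflammatory messenger RNAs, stood at 2.40 against 19.8 RPKM. Spop, an adaptor of a ubiquitin ligase, stood at 14.3 against 79.6 RPKM. All 3 had an adjusted p under 0.05 by limma after both operations, and with the length trend removed their log2 fold changes were -3.09, -2.54 and -2.29 in this order.

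Gm10263, a short transcript outside the naming rule, had the largest change of all called genes in both comparisons of band with sham. It stood at 123 and 134 RPKM in sham input and at 3.66 and 4.74 RPKM in band input (limma, log2 fold change -4.64, SE 0.27, adjusted p = 0.000655). In TRAP RNA it stood at 248 and 237 RPKM after sham surgery and at 3.89 and 8.30 RPKM after banding (limma, log2 fold change -5.17, adjusted p = 0.000434). Without surgery the CAG libraries gave 36.4 RPKM for input and 22.7 RPKM for TRAP, and the Tie2 libraries 605 and 2866 RPKM.

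Shorter transcripts had higher TRAP to input ratios in CAG hearts, with slopes from -0.26 to -0.17 per doubling of length on the log2 scale. A length trend that differs from library to library whatever the fraction is argued against, since the steepest slope between libraries of 1 group and fraction was 0.0373, below the least steep of those slopes in size. Loss of long RNA in the pulldown in every mouse line would give a negative slope in Tie2 hearts too, and over 108 ribosomal protein, translation factor and chaperone genes it was -0.24 (SE 0.10), against -0.25 (SE 0.06) in CAG hearts without surgery. These lists differ in length and in their Tie2 ratio, and with the list as a term the slopes were 0.07 (SE 0.11) and -0.08 (SE 0.07), while over all 5468 genes the Tie2 slope was -0.01, so this loss stays open. Lower RNA integrity in TRAP RNA before poly(A) selection stays open, because 0 tables of coverage along transcripts were analysed here, and no biological explanation was tested.

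Atrial transcripts were higher in the inputs of hearts without surgery than in sham inputs, with Myl7, the atrial myosin light chain, at 2724 RPKM in CAG and 5867 RPKM in Tie2 input against 15.8 ± 0.475 RPKM, and Sln, sarcolipin, at 1622 and 2135 against 7.45 RPKM. The pattern was not limited to natriuretic peptide expression, as the median of the atrial genes other than Nppa was 60.5-fold on RPKM + 1. Those genes are part of the pattern itself, so this is no separate test. An overall difference in cardiomyocyte RNA is argued against by the cardiomyocyte list, whose median was 0.985-fold. Atrial tissue in the hearts without surgery and not in those with surgery stays open, since the 7 of 7 atrial genes higher in both inputs, with a median of 22.1-fold, are the pattern itself. A difference in sex stays open too, since the labels give 0 surgery groups with libraries of different sex. The Y-linked Ddx3y stood at 0.0487 and 0.283 RPKM in the inputs without surgery against 3.28 and 2.84 RPKM in sham inputs. Xist, which female cells express, was low in all 4 but higher without surgery, at 0.0883 and 0.0432 against 0.00120 and 0.00533 RPKM. The levels of Xist are too low to decide this. Surgery itself also differs between these hearts and was not tested apart.

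Ferritin transcripts were lower in TRAP than in input after sham surgery, with Fth1 at 708 against 2601 RPKM (limma, log2 fold change -1.88, SE 0.10, adjusted p = 8.14e-05) and Ftl1 at 35.8 against 122 RPKM (-1.74, SE 0.16, adjusted p = 0.000677), both uncertain because of pseudogenes. The transcript length trend is argued against by its direction. Fth1 and Ftl1 have 866 and 968 bases, and genes of 500 to 1000 bases had median log2 ratios of 0.44 and 0.37 in the sham pairs. With the trend removed Fth1 stood at -2.13 and Ftl1 at -1.98. For transcripts of this length the removal could only deepen a fall, so it is no separate test. Lower recovery of RNA of macrophages and leukocytes, at the level of that list as a whole, is argued against too. The lower quartile of the list was -0.97, a smaller fall than that of either gene. A quartile does not bound the recovery of every leukocyte type. Other blood cells are not covered either, and the erythroid list fell further, at a median of -3.58. Reads shared with pseudogenes stay open, and no biological explanation is weighed here. In the single Tie2 pair Fth1 stood at -2.18 and Ftl1 at 1.06.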
